A study of Mus musculus with 21 samples.

How the data were processed

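RAW 264.7 cells were exposed for 2 h to amorphous silica of 10 nm (5, 20 and 50 µg/ml) or 500 nm (250, 500 and 1000 µg/ml) in serum-free medium, per the labels. Untreated cells were the control, and each of the 7 groups had 3 arrays, 21 in all, grouped by the sample titles and source names. Per the labels' protocols, total RNA was extracted with a column kit and copied into biotin-labelled RNA by an oligo-dT primed reaction, which favours the 3 prime ends of transcripts, and hybridised to an Affymetrix mouse array. The protocols give different plates and attachment times for growth and treatment, so the culture vessel is not settled. The labels do not say that the replicates were separate cultures, so the p-values measure the spread between these arrays, which may be technical. Nor do they say whether untreated cells were moved to serum-free medium, so effects of that change and of the particles were not separated.

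The deposited table holds 1 value per probe set and array on a log10 scale, made by the authors with RMA, per the submitters' processing notes; the version of RMA and its settings are not given in the sources used here. RMA usually subtracts background, gives arrays run together a common distribution and summarises each probe set, which removes a change shared by most genes and compresses changes of dim probe sets. The deposited arrays do not share one distribution (SD 2.46 to 2.67 on the log2 scale), so whether all 21 were run together is not known. The log base was not stated and was read from the values, which ran from 0.641 to 4.34. Base 10 puts the brightest value at 22019 intensity units, within a scanner's range, while base 2 and base e would put it at 20.3 and 76.9. The bioB and cre hybridisation controls, added at very different amounts, differed by 1.53 units, which is 33.9-fold in base 10 and 2.89-fold in base 2. The values were multiplied by 3.32 to give log2 values from 2.13 to 14.43. The plan had foreseen a transformation only of linear values. This rescaling changes the size of log2 changes but neither p-values nor counts without a size bound. Every fold change printed rests on that reading of the base. Arrays have no count or depth, and their number limits the precision.

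Of the 22690 probe sets, 64 were controls; 20393 had 1 gene symbol, 691 several and 1606 none in the platform annotation, which can be old. Of those with 1 symbol, 20364 matched the mouse reference table (GRCm38.p6) by gene ID and 0 symbols needed an update. Genes were taken from 20380 probe sets and each gene was represented by the probe set with the highest mean over the 21 arrays, which gave 12393 genes, 4956 of them with several probe sets. Probe sets with several or no symbols were left out of the gene tests. The reference table served for names alone, without coordinates.

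The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on log2 values, group as the only factor, all 21 arrays sharing one estimate of the spread, 14 residual and 4.80 prior degrees of freedom; the median residual SD was 0.184). Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the genes of a comparison, with a gene called at an adjusted p under 0.05. The 11 comparisons were the 6 doses against untreated cells, the slope of the group means on log2 dose within each size, and 10 nm against 500 nm at the low doses, at the high doses and at the 10 nm mid and 500 nm high doses. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

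For each of 22 gene lists (8 to 32 measured members; 533 of 596 planned genes measured, 8 of them in several lists), limma's camera compared the list with all other genes at a preset inter-gene correlation of 0.01, and again with the correlation estimated from the residuals, adjusted over the 22 lists of a comparison. The lists were inflammatory cytokines and chemokines, NF-kB pathway feedback, immediate early, NRF2 antioxidant, metal response, heat shock, unfolded protein and integrated stress response, sterol synthesis, LXR target, mitotic, S phase, p53, lysosome, phagocytic and scavenger receptor, interferon-stimulated, hypoxia and glycolysis, growth factor, matrix and protease, inflammasome and cell death, actin and SRF target, oxidative phosphorylation, ribosomal protein and short-lived transcription regulator genes. A further 8 lists held markers of macrophages, neutrophils, dendritic cells, T cells, B cells, fibroblasts, epithelial cells and osteoclasts, adjusted over the 8. The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined, except where stated. That rule took, among called genes whose 3 arrays of one group all lay beyond the 3 of the other, the 10 largest rises and falls at each high dose, 5 each between the high doses and 3 each in the other comparisons, and from each list the 3 members with the largest change among those called at a high dose, or the one with the smallest p.

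Alternatives were a block for the replicate number, a trended and robust variance prior, a fit on the compared groups alone, leaving out the dimmest 40% of genes, quantile normalization again, arrays centred on their median, the mean of a gene's probe sets, all probe sets singly, array weights, stricter thresholds, each array left out in turn and 2 other list tests. Leaving out all replicate 3 arrays, the 3 prime minus 5 prime signal of 4 control probe pairs as a covariate, and rescaling arrays to equal mean and SD were chosen after the arrays were seen. Arrays of the same replicate number were checked for deviating together from their group means. Every same-number pair correlated above 0.1 for untreated cells with the 10 nm mid dose (0.529, 0.434 and 0.68 for replicates 1, 2 and 3) and the 10 nm high dose (0.457, 0.526 and 0.716) and for the 2 high doses with each other (0.282, 0.569 and 0.704), and the blocked count is given beside those 3 comparisons. This pairing is read from the data, since the labels give the number alone.

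The tests were tried on 12393 simulated genes with 200 changed. At the 10 nm high dose 43.3%, 91.0% and 100% of the genes changed by 0.5, 1 and 2 log2 units were recovered, with 4 unchanged genes called. At the 500 nm high dose the shares were 29.9%, 88.1% and 97.0% with 11 such calls, and between the high doses 38.8%, 88.1% and 97.0% with 3. A list shifted by 0.5 log2 units at the 10 nm high dose was found in 10 of 10 runs. The 0 others called do not bound false calls in the real arrays, whose genes vary together (up to 6 in other splits). Correlation from shared controls was measured with 100 draws of unchanged groups.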

Results

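The arrays measured messenger RNA in RAW 264.7 cells, a macrophage-like mouse tumour line, after 2 h with amorphous silica particles of 10 nm or 500 nm. The 10 nm particles were given at 5, 20 and 50 µg/ml and the 500 nm particles at 250, 500 and 1000 µg/ml, called the low, mid and high dose of each size. Untreated cells were the common control, and each of the 7 groups had 3 arrays. By its title the series concerns how macrophages respond to silica nanoparticles. The comparisons were each dose against untreated cells, the dose trend of each size and 3 pairs of the sizes. The nominal surface area, dose divided by diameter for equally dense spheres, stood at 1, 4 and 10 times the low dose for 10 nm and 1, 2 and 4 times for 500 nm silica. The low doses therefore had equal nominal area, as did the 10 nm mid dose and the 500 nm high dose, while the high doses did not.

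All 12393 genes had a value on each of the 21 arrays. Across genes, which are not independent replicates, arrays correlated at 0.983 to 0.998 within and 0.969 to 0.998 between groups. No pair was identical. The first 2 principal components held 35.0% and 27.2% of the variance. In all 7 groups the replicate 3 array had the lowest SD of its values and the highest score on the first component of the deviations from the group means, which held 57.3% of that variance. The 3 prime minus 5 prime signal of control transcripts, a log2 index that rises as RNA degrades, was highest in replicate 3 in 4 of the 7 groups. Its mean was 1.0 ± 0.59 in untreated cells (SD, n = 3 each). With 10 nm and 500 nm silica it was 0.96 ± 0.41 and 0.85 ± 0.31 at the high doses. At the low doses it was 1.17 ± 0.11 and 0.80 ± 0.17. The log2 SD on an array averaged 2.64 in untreated cells and 2.55 and 2.58 at the high doses, 10 nm first.

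**Figure D1:**
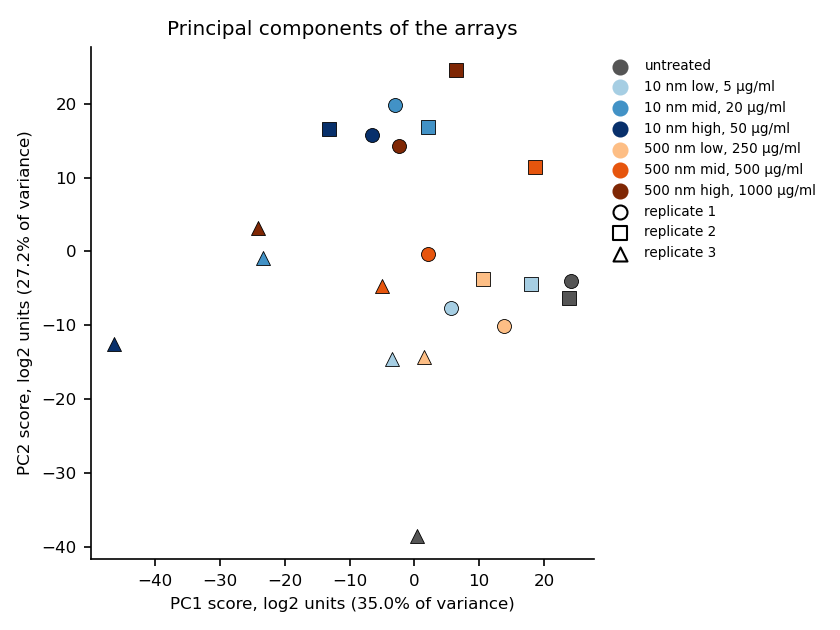
Each of the 21 arrays is placed by its scores on the first principal component (horizontal axis, 35.0% of the variance) and the second (vertical axis, 27.2%); colours give the 7 groups and symbols the replicate number. The high-dose arrays of each particle size lie apart from the untreated arrays, and in each group the replicate 3 array has the lowest score on both axes.

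At the high dose of 10 nm silica, the largest rises were those of a cytoskeletal regulator, chemokines, kinase regulators and transcription factors. Rhob, a small GTPase that acts on the actin cytoskeleton, rose 35.3-fold, from 5.74 ± 0.20 to 10.88 ± 0.53 on the log2 scale (SD, n = 3 arrays each; log2 change 5.14 ± 0.27 SE, limma adjusted p = 8.5e-11). Cxcl2, a chemokine that attracts neutrophils, rose 34.6-fold, from 6.95 ± 0.24 to 12.06 ± 0.26 (log2 change 5.11 ± 0.13, adjusted p = 5.78e-16). Dusp1, a phosphatase that inactivates MAP kinases, rose 19.7-fold (log2 change 4.3 ± 0.09, adjusted p = 1.41e-16). The transcription factor gene Klf2 rose 17.8-fold (log2 change 4.16 ± 0.13, adjusted p = 2.9e-14). The next largest rises were those of the transcription factors Egr2 (3.71 ± 0.15), Nr4a1 (3.61 ± 0.18) and Atf3 (3.54 ± 0.11), the chemokines Ccl2 (3.61 ± 0.30) and Ccl4 (3.42 ± 0.12) and the kinase Plk2 (3.28 ± 0.26, log2 change ± SE). Among the falls, the zinc finger gene Zfp958 was 4.97-fold lower (log2 change -2.31 ± 0.16, adjusted p = 4.65e-09). The transcriptional repressor gene Gfi1 was 4.19-fold lower (-2.07 ± 0.16, adjusted p = 2.84e-08) and Pde4b, a phosphodiesterase that breaks down cyclic AMP, 4.15-fold lower (-2.05 ± 0.15, adjusted p = 1.18e-08). The other large falls were those of 4632415L05Rik (-1.99 ± 0.23), Sesn1, a stress-responsive sestrin (-1.97 ± 0.14), Capn7 (-1.87 ± 0.12) and Zfp61 (-1.71 ± 0.16). They were followed by the thioredoxin inhibitor Txnip (-1.71 ± 0.16), Stambp (-1.70 ± 0.14) and Rin2 (-1.70 ± 0.13).

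Of the 12393 genes, 2506 changed at the 10 nm high dose (939 higher and 1567 lower), 281 of them at least 2-fold (139 higher and 142 lower). In 2338 of the 2506, all 3 treated arrays lay beyond all 3 untreated arrays, which chance gives for 10% of unchanged genes but which choosing genes by a test on the same arrays favours. The split into higher and lower genes moved to 1853 and 1100 with each array centred on its median, which shifted the median of all genes from 0.036 to 0.14 log2, and to 3249 and 3005 with array weights. With the replicate number as a block, 4544 genes changed (2153 higher and 2391 lower). Without untreated replicates 1 and 2 and 10 nm high dose replicate 3, each in turn, 592, 543 and 505 genes were higher.

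Grouped by the gene lists, the immediate early genes, which cells switch on within minutes of a stimulus, responded most. At the 10 nm high dose 29 of 32 measured members rose and 0 fell (30 and 0 adjusted over the list alone; median 2.21, adjusted p = 2.15e-43 with the preset correlation and 7.49e-06 estimated, meaning with the estimated one). Of the inflammatory cytokines and chemokines, 13 of 25 rose and 1 fell (13 and 1 adjusted over the list alone; median 0.44, adjusted p = 1.23e-10, 2.88e-05 estimated). Of the growth factors, matrix genes and proteases, 9 of 24 rose and 0 fell (10 and 0 adjusted over the list alone), among them Hbegf, a growth factor of the EGF family (2.73), and Plaur, the urokinase receptor (2.19). The median was 0.28 (adjusted p = 5.75e-05, 0.00863 estimated). These 3 lists passed with both correlations, and 6 and 8 lists passed estimated after quantile normalization and rescaling. Of the S phase and DNA replication genes, 0 of 27 rose and 9 fell (0 and 10 adjusted over the list alone), including the thymidylate synthase gene Tyms (-1.58) and the cyclin gene Ccne2 (-0.55). The median was -0.29 (adjusted p = 2.26e-05, 0.174 estimated). Of the mitotic genes, 0 of 28 rose and 7 fell (0 and 8 adjusted over the list alone), including Aurkb (-0.63). The median was -0.21 (adjusted p = 0.0154, 0.375 estimated). The preset p was 0.17 after quantile normalization and 0.293 after rescaling. Calls ended without 1 array (limma's adjusted p) for Ccne2 (0.0959 without untreated replicate 3 and 0.0584 without 10 nm high dose replicate 3). Another probe set of Tyms had the opposite sign.

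Of the genes of the unfolded protein and integrated stress response, 9 of 30 rose and 1 fell (9 and 1 adjusted over the list alone), among them Ppp1r15a, which restores translation after stress (2.10), and Trib3 (0.47). The median was 0.15 (adjusted p = 0.00993, 0.326 estimated). Of the transcription regulators with short-lived mRNAs, 10 of 28 rose and 5 fell (11 and 6 adjusted over the list alone), with rises of Sertad1 (1.82) and Bhlhe40 (1.81). The median was 0.23 (adjusted p = 0.00492, 0.0972 estimated). Of the actin and SRF target genes, 5 of 27 rose and 1 fell (5 and 1 adjusted over the list alone), among them Arc (2.05) and Tagln (0.61). The median was 0.12 (adjusted p = 0.0308, 0.0933 estimated). Of the oxidative phosphorylation genes, 0 of 31 rose and 2 fell (0 and 2 adjusted over the list alone), namely Ndufs1 (-0.35) and Atp5c1 (-0.31). The median was -0.16 (adjusted p = 0.0236, 0.446 estimated). Quantile normalization gave an adjusted p of 0.0713, and rescaling turned the median to 0.060 (adjusted p = 0.585). Calls ended without 1 array (limma's adjusted p) for Trib3 (0.0897 without untreated replicate 3 and 0.0856 without 10 nm high dose replicate 2) and Atp5c1 (0.0517 without untreated replicate 1). Another probe set of Trib3 had the opposite sign.

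The other 13 lists did not pass at the 10 nm high dose. For the NF-kB pathway feedback genes (6 higher and 8 lower of 24, 6 and 8 adjusted over the list alone, median -0.17, adjusted p = 0.544) the mean was 0.081 and the test pointed down. Gadd45b rose (2.59), as did Traf1 (0.69) and Rel (0.52). For NRF2 antioxidant genes (2 higher and 1 lower of 21, 2 and 1 adjusted over the list alone, median -0.035, adjusted p = 0.532) the mean was 0.10 and the test pointed up. Hmox1, which breaks down haem, rose (1.20), and the cystine transporter gene Slc7a11 had a log2 change of -0.035 ± 0.13 (adjusted p = 0.861). For sterol synthesis the values were 1 higher and 1 lower of 20, 0 and 1 adjusted over the list alone, median -0.13, adjusted p = 0.16; Hsd17b7 rose (0.52) and Hmgcs1 stood at 0.085 ± 0.18 (adjusted p = 0.76). For hypoxia and glycolysis genes (6 higher and 4 lower of 25, 7 and 4 adjusted over the list alone, median -0.027, adjusted p = 0.411) the mean was 0.11 and the test pointed up, with a rise of Ndrg1 (2.87) and a fall of Pfkfb3 (-0.95). For inflammasome and cell death genes (3 higher and 6 lower of 21, 4 and 7 adjusted over the list alone, median 0.042, adjusted p = 0.434) the mean was -0.086 and the test pointed down. Bcl2l11, which promotes apoptosis, rose (1.62) and Naip5 fell (-0.52). Calls ended without 1 array (limma's adjusted p) for Rel (0.0561 without untreated replicate 1, and 0.0745 and 0.0684 without 10 nm high dose replicates 1 and 2), Hmox1 (0.0507 without 10 nm high dose replicate 2), Hsd17b7 (0.241 without untreated replicate 1 and 0.189 without 10 nm high dose replicate 3) and Naip5 (0.193 without untreated replicate 3, and 0.0888 and 0.132 without 10 nm high dose replicates 1 and 2).

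For interferon-stimulated genes the values were 1 higher and 5 lower of 31, 1 and 5 adjusted over the list alone, median -0.12, adjusted p = 0.0785, with falls of Ifit2 (-1.38) and Cmpk2 (-0.52). For p53 and DNA damage genes they were 8 higher and 5 lower of 22, 8 and 5 adjusted over the list alone, median 0.15, adjusted p = 0.244, with rises of Sesn2 (1.72) and Btg2 (1.76). LXR targets gave 2 higher and 4 lower of 17, 3 and 5 adjusted over the list alone, median -0.079, adjusted p = 0.411, with falls of the cholesterol exporter gene Abca1 (-1.29) and of Scd2 (-1.08). Phagocytic and scavenger receptors gave 2 higher and 4 lower of 27, 2 and 7 adjusted over the list alone, median -0.067, adjusted p = 0.411, with a rise of Olr1 (2.44) and a fall of Tlr4 (-1.08). Metal response genes gave 3 higher and 1 lower of 8, 3 and 1 adjusted over the list alone, median 0.051, adjusted p = 0.311, with rises of Mt2 (0.97) and the zinc exporter gene Slc30a1 (1.17). Heat shock genes gave 2 higher and 0 lower of 20, 2 and 0 adjusted over the list alone, median 0.085, adjusted p = 0.244, with rises of Dnajb1 (0.84) and Hspa8 (0.33). Lysosome genes gave 3 higher and 2 lower of 29, 3 and 2 adjusted over the list alone, median 0.050, adjusted p = 0.532, with a rise of Ctsl (0.73), and ribosomal proteins 0 higher and 1 lower of 24, 0 and 0 adjusted over the list alone, median -0.044, adjusted p = 0.427, with a fall of Rpl14 (-0.45). After rescaling of the arrays the ribosomal protein median was 0.23 (adjusted p = 0.00198), and the lysosome, hypoxia, NRF2, metal and heat shock lists also passed. Calls ended without 1 array (limma's adjusted p) for Cmpk2 (0.0551 without untreated replicate 3 and 0.0577 without 10 nm high dose replicate 1), Hspa8 (0.0591 without untreated replicate 1 and 0.0622 without 10 nm high dose replicate 3) and Rpl14 (0.0833 and 0.0896 without untreated replicates 1 and 2, and 0.0523 and 0.127 without 10 nm high dose replicates 2 and 3). Another probe set of Cmpk2 had the opposite sign, and others of Hspa8 gave 0.13 to 2.80.

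**Figure D2:**
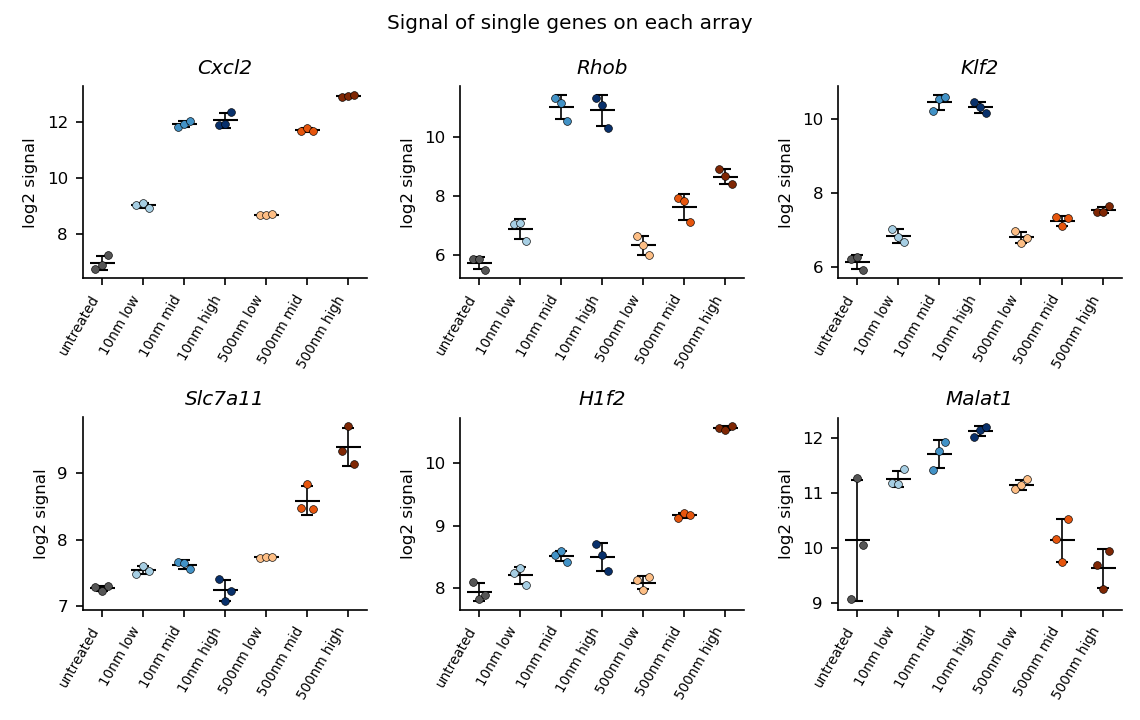
The log2 signal of Cxcl2, Rhob, Klf2, Slc7a11, H1f2 and Malat1 on each array (vertical axes) in the 7 groups (horizontal axes), where points are arrays, lines the group means and bars the SD (n = 3). Rhob and Klf2 were higher at the 10 nm than at the 500 nm high dose. Slc7a11 and H1f2 showed the reverse.

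At the high dose of 500 nm silica, Cxcl2 rose 63.5-fold, from 6.95 ± 0.24 to 12.94 ± 0.04 (SD, n = 3 arrays each; log2 change 5.99 ± 0.13 SE, limma adjusted p = 3.99e-17). Dusp1 rose 21.6-fold (4.43 ± 0.09, adjusted p = 3.99e-17) and Plk2 15.7-fold (3.97 ± 0.26, adjusted p = 1.94e-09). Atf3 (3.58 ± 0.11), the stress gene Gadd45b (3.41 ± 0.12), Maff (3.34 ± 0.15) and Ccl4 (3.22 ± 0.12) followed. Next were Rhob (2.91 ± 0.27), Rgs1 (2.71 ± 0.09) and Hilpda, which acts on lipid droplets (2.69 ± 0.26). Abca1 was 4.36-fold lower (-2.12 ± 0.22, adjusted p = 1.37e-06). The reductase gene Akr1b10 was 3.99-fold lower (-1.99 ± 0.13, adjusted p = 2.98e-09) and Rin2 3.96-fold (-1.99 ± 0.13, adjusted p = 2.66e-09). Ptpro (-1.98 ± 0.14), Calhm2 (-1.85 ± 0.12) and Themis2 (-1.77 ± 0.12) followed. Next came Sgpp1 (-1.72 ± 0.11), Spata13 (-1.71 ± 0.29), Calcrl (-1.63 ± 0.23) and Sesn1 (-1.62 ± 0.14). Other probe sets of Abca1 (-0.52 and -0.34), Akr1b10 (-0.51) and Calcrl (-0.39) fell less, those of Sesn1 more.

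In all, 1898 genes changed at the 500 nm high dose (658 higher and 1240 lower), 252 of them at least 2-fold (117 higher and 135 lower). Centring each array on its median gave 1205 higher and 895 lower, and moved the median of all genes from 0.073 to 0.17 log2. The block gave 1562 higher and 1871 lower and array weights 2652 and 2202, and without 500 nm high dose replicate 3 there were 420 higher genes.

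Of the immediate early genes, 28 of 32 rose and 1 fell (30 and 1 adjusted over the list alone) at the 500 nm high dose. The median was 1.46 (adjusted p = 2.51e-33, 1.83e-05 estimated). Of the cytokines and chemokines, 14 of 25 rose and 0 fell (15 and 0 adjusted over the list alone; median 0.41, adjusted p = 3.06e-13, 1.52e-05 estimated). Of the NF-kB pathway feedback genes, 9 of 24 rose and 1 fell (11 and 2 adjusted over the list alone), among them Rel (1.98) and Traf1 (1.83). The median was 0.38 (adjusted p = 1.94e-06, 0.0264 estimated). Of the sterol synthesis genes, 12 of 20 rose and 1 fell (12 and 1 adjusted over the list alone), among them Hmgcs1, which acts early in the mevalonate pathway (1.03), and Hsd17b7 (1.01). The median was 0.58 (adjusted p = 3.95e-07, 0.00219 estimated). Of the growth factors, matrix genes and proteases, 8 of 24 rose and 0 fell (8 and 0 adjusted over the list alone), including the urokinase gene Plau (2.37). The median was 0.22 (adjusted p = 6.17e-05, 0.00727 estimated). Of the LXR targets, 1 of 17 rose and 6 fell (1 and 7 adjusted over the list alone), with falls of Abca1 and Scd2 (-0.56) and a rise of Plin2 (0.29). The median was -0.41 (adjusted p = 0.00778, 0.0264 estimated). These 6 lists passed with both correlations, and 9, 8 and 8 passed estimated after quantile normalization, centring and rescaling. Calls ended without 1 array (limma's adjusted p) for Plin2 (0.079 and 0.0887 without untreated replicates 2 and 3, and 0.0671 and 0.0955 without 500 nm high dose replicates 1 and 2).

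The other 7 lists that passed with the preset correlation at the 500 nm high dose did not pass with the estimated one as deposited. The block ended the calls of the p53 (0.0538), interferon (0.0691) and transcription regulator lists (0.0582, adjusted p), while the stress response list passed estimated with it (0.0349). Of the NRF2 antioxidant genes 6 of 21 rose and 0 fell (6 and 0 adjusted over the list alone), among them Slc7a11 (2.12), Hmox1 (1.86) and Srxn1 (1.69). The median was 0.16 (adjusted p = 0.0038, 0.0955 estimated). Of the unfolded protein and stress response genes 13 of 30 rose and 2 fell (13 and 3 adjusted over the list alone), among them Ddit3 (2.01) and Trib3 (1.80). The median was 0.21 (adjusted p = 0.000125, 0.0966 estimated). Of the S phase genes 1 of 27 rose and 7 fell (1 and 8 adjusted over the list alone), including Tyms (-1.54) and Cdc6 (-0.95). The median was -0.22 (adjusted p = 0.000145, 0.158 estimated). Of the mitotic genes 1 of 28 rose and 6 fell (1 and 6 adjusted over the list alone), including Cenpf (-0.72) and Mki67 (-0.64). The median was -0.17 (adjusted p = 0.00383, 0.249 estimated). Rescaling gave an adjusted p of 0.0656. Of the p53 and DNA damage genes 8 of 22 rose and 4 fell (9 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.0365, 0.0863 estimated). Centring on the array median gave an adjusted p of 0.0747. Of the interferon-stimulated genes 3 of 31 rose and 5 fell (3 and 9 adjusted over the list alone). Ifit2 (-0.95) and Cmpk2 (-1.06, other probe set -0.0014) fell and Cxcl10 (1.76) rose. The median was -0.26 (adjusted p = 0.0479, 0.122 estimated). After quantile normalization the adjusted p was 0.208 and after rescaling 0.0656. Of the transcription regulators 9 of 28 rose and 4 fell (12 and 4 adjusted over the list alone; median 0.23, adjusted p = 0.0492, 0.196 estimated). Centring gave an adjusted p of 0.0819. Another probe set of Tyms had the opposite sign.

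The remaining 9 lists did not pass at the 500 nm high dose. Phagocytic and scavenger receptors gave 4 higher and 5 lower of 27, 5 and 8 adjusted over the list alone, median -0.033, adjusted p = 0.796, with a rise of Clec4e (1.65). Inflammasome and cell death genes gave 4 higher and 3 lower of 21, 4 and 4 adjusted over the list alone, median 0.14, adjusted p = 0.796, with a fall of Naip5 (-1.07). Lysosome genes gave 1 higher and 5 lower of 29, 1 and 6 adjusted over the list alone, median 0.057, adjusted p = 0.452, with a mean of -0.0089, a test that pointed down and a fall of Lamp2 (-0.63). Hypoxia genes gave 3 higher and 3 lower of 25, 5 and 4 adjusted over the list alone, median 0.019, adjusted p = 0.791, with a fall of Pdk1 (-0.54), and metal response genes 2 higher and 1 lower of 8, 2 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.419, with a rise of the iron exporter gene Slc40a1 (1.82). Heat shock genes gave 0 higher and 1 lower of 20, 0 and 0 adjusted over the list alone, median 0.080, adjusted p = 0.791, with a fall of Hspa1b (-0.69). Actin and SRF targets gave 1 higher and 0 lower of 27, 1 and 0 adjusted over the list alone, median 0.10, adjusted p = 0.326, oxidative phosphorylation 0 higher and 0 lower of 31, 0 and 0 adjusted over the list alone, median 0.053, adjusted p = 0.791, and ribosomal proteins 0 higher and 0 lower of 24, 0 and 0 adjusted over the list alone, median 0.031, adjusted p = 0.972. After rescaling, oxidative phosphorylation (median 0.20) and ribosomal proteins (0.21) passed. Calls ended without 1 array (limma's adjusted p) for Lamp2 (0.055 without untreated replicate 3), Pdk1 (0.0587 without untreated replicate 3 and 0.056 without 500 nm high dose replicate 2) and Hspa1b (0.196 without untreated replicate 3, and 0.11 and 0.106 without 500 nm high dose replicates 1 and 3).

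**Figure D3:**
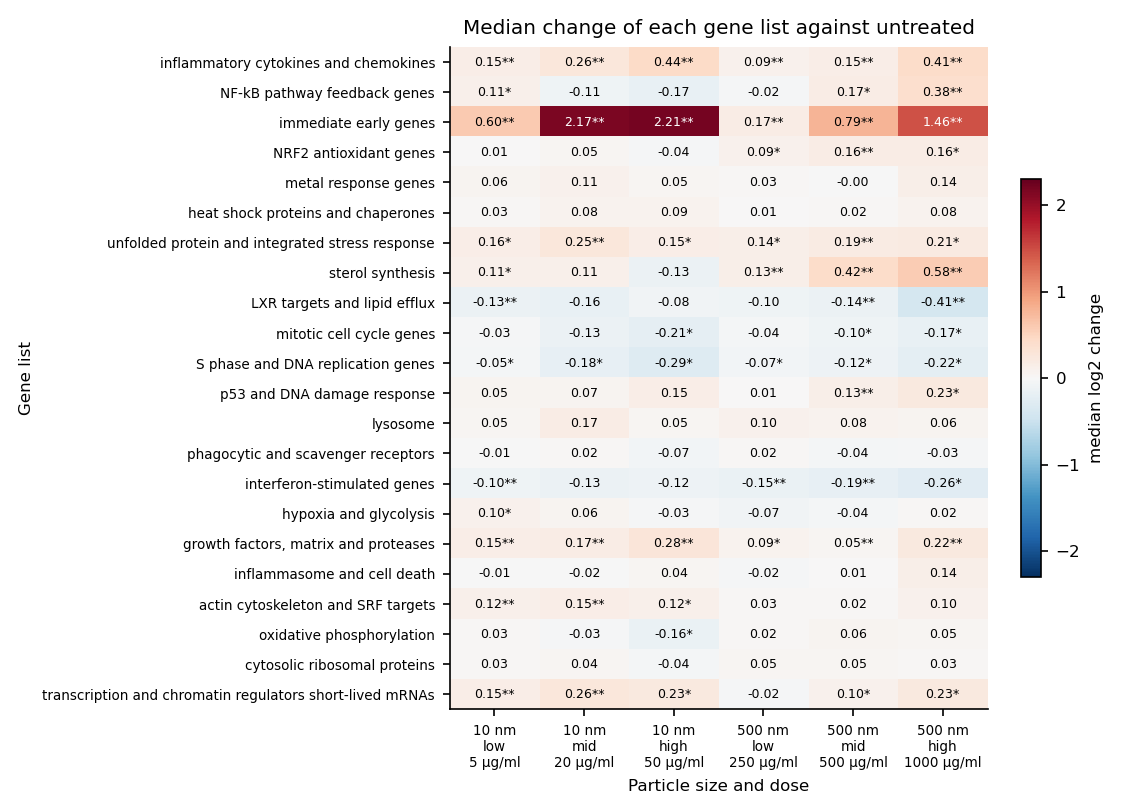
Median log2 change of the measured members of the 22 gene lists (vertical) in the 6 dose groups against untreated cells (horizontal), as colour and number; a single star marks an adjusted p under 0.05 with the preset correlation and a double star one that also passed with the estimated correlation.

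At the low dose of 10 nm silica, Cxcl2 rose 4.19-fold (log2 change 2.07 ± 0.13, n = 3, limma adjusted p = 5.71e-09), Atf3 4.17-fold (2.06 ± 0.11) and Ccl4 3.82-fold (1.93 ± 0.12). The transcription factor gene Klf4 was 2.35-fold lower (-1.23 ± 0.17, adjusted p = 0.000284), and Gpr155 (-0.80 ± 0.15) and Zfp53 (-0.78 ± 0.17) fell less. The call of Gpr155 ended with adjusted p = 0.0609 without untreated replicate 2 and 0.0502 without 10 nm low dose replicate 3. That of Zfp53 ended with adjusted p = 0.0607, 0.119 and 0.165 without untreated replicates 1, 2 and 3, and 0.202 and 0.243 without 10 nm low dose replicates 1 and 3. In all, 95 genes changed (75 higher and 20 lower), 19 of them at least 2-fold (18 higher and 1 lower), and without 10 nm low dose replicate 1 the count was 60 (5 lower); 10 were lower without untreated replicate 1 and 9 without 10 nm low dose replicate 3.

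At the mid dose of 10 nm silica, Rhob rose 37.9-fold (5.24 ± 0.27, limma adjusted p = 6.34e-11), Cxcl2 31.6-fold (4.98 ± 0.13) and Klf2 19.7-fold (4.3 ± 0.13; n = 3). Gfi1 (-2.11 ± 0.16), Zfp958 (-2.06 ± 0.16) and Sesn1 (-1.89 ± 0.14) fell. In all, 1315 genes changed (399 higher and 916 lower; 210 at least 2-fold, 125 higher and 85 lower), and 2235 with the replicate number as a block. Without 10 nm mid dose replicate 1, 568 were lower. The split was 589 higher and 640 lower with arrays centred on their median and 472 and 696 after quantile normalization. Of the lists, 12 passed with the preset correlation at the low dose, 7 of which also passed with the estimated one, and 7 and 6 at the mid dose. Rescaling gave 11 estimated at the low dose. At the mid dose quantile normalization and rescaling gave 12 and 13, and rescaling and centring 11 and 4 estimated. The immediate early gene median was 0.60, 2.17 and 2.21 at the 3 doses (13, 29 and 29 of 32 members rose). At the mid dose, 11 of 30 unfolded protein and stress response genes rose and 0 fell (13 and 1 adjusted over the list alone; median 0.25, adjusted p = 1.11e-06, 0.0447 estimated). With the block, the mitotic list moved from an adjusted p of 0.0624 to 0.0428 and the lysosome list from 0.0924 to 0.0477 at the mid dose.

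Across the 3 doses of 10 nm silica, Rhob rose by 1.28 ± 0.08 log2 units per doubling of the dose (limma adjusted p = 2.66e-09), Klf2 by 1.10 ± 0.04 and Fos by 1.10 ± 0.06. The slopes were -0.56 ± 0.05 for Zfp958, -0.53 ± 0.05 for Gfi1 and -0.52 ± 0.07 for 4632415L05Rik. The trend was called for 1509 genes (388 with rising and 1121 with falling values), and for 837 (237 and 600) without 10 nm low dose replicate 2. The split was 831 and 610 with centred arrays, 500 and 710 after quantile normalization and 519 and 876 after rescaling. Of the 939 genes higher at the high dose, 350 were also called higher at the mid dose and 65 at the low dose. Of the 1567 lower genes, 875 and 18 were.

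At the low dose of 500 nm silica, Atf3 rose 3.83-fold (log2 change 1.94 ± 0.11, n = 3, limma adjusted p = 4.64e-09), the chemokine receptor gene Cxcr4 3.52-fold (1.81 ± 0.16) and Tent5c 3.45-fold (1.79 ± 0.16). Klf4 (-1.10 ± 0.17), Egr2 (-0.92 ± 0.15) and Pde4b (-0.84 ± 0.15) fell. The call of Pde4b ended with adjusted p = 0.0657 without untreated replicate 2, and 0.0768 and 0.062 without 500 nm low dose replicates 1 and 2. In all, 53 genes changed (43 higher and 10 lower), 14 of them at least 2-fold (13 higher and 1 lower), and 35 without 500 nm low dose replicate 2 (3 lower; 6 and 5 were lower without untreated replicates 1 and 3). At the mid dose Cxcl2 rose 27.4-fold (4.78 ± 0.13, adjusted p = 4.07e-15), Plk2 (3.33 ± 0.26) and Dusp1 (3.21 ± 0.09) rose. Akr1b10 (-1.36 ± 0.13), Tyms (-1.30 ± 0.15) and Ptpro (-1.28 ± 0.14) fell. There 343 genes changed (156 higher and 187 lower; 60 at least 2-fold, 52 higher and 8 lower), and 225 and 216 without 500 nm mid dose replicate 1 and 3 (111 and 114, and 119 and 97). More genes were higher than lower also without untreated replicate 3 (145 and 106) or all replicate 3 arrays (164 and 98), after quantile normalization (188 and 160), with centring (175 and 162), with array weights (1322 and 995) and in the fit on these groups alone (82 and 42).

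Of the lists, 8 passed with the preset correlation at the 500 nm low dose, 4 of them also with the estimated one (6, 6 and 7 after quantile normalization, centring and rescaling), and 13 and 9 at the mid dose. The immediate early gene median was 0.17, 0.79 and 1.46 at the 3 doses of 500 nm silica and that of sterol synthesis 0.13, 0.42 and 0.58. At the mid dose, 8 of 20 rose and 0 fell (12 and 0 adjusted over the list alone) in the sterol list (adjusted p = 3.47e-11, 0.000196 estimated). Over the doses, Cxcl2 rose by 2.13 ± 0.06 log2 units per doubling (limma adjusted p = 1.68e-14), Dusp1 by 1.83 ± 0.05 and Gadd45b by 1.28 ± 0.06. The slopes of Rin2, Abca1 and the cannabinoid receptor gene Cnr2 were -0.81 ± 0.07, -0.81 ± 0.11 and -0.77 ± 0.11. The trend was called for 1016 genes (351 rising and 665 falling; 564 and 487 with centred arrays, 1709 and 1637 with array weights), and for 646 and 650 without 500 nm low dose replicate 1 and 3 (246 and 400, and 210 and 440), with 233 rising without replicate 2. Of the 658 genes higher at the high dose, 147 were also called at the mid dose and 35 at the low dose, and of the 1240 lower genes 183 and 8.

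**Figure D4:**
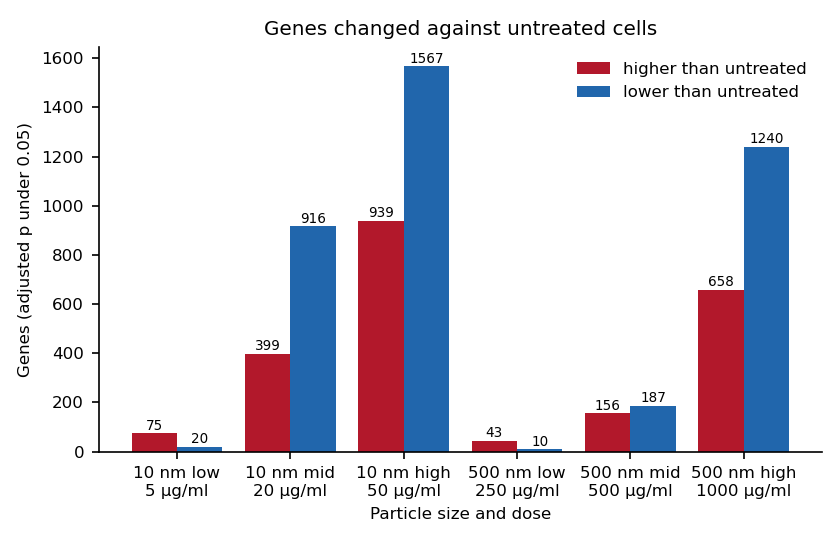
Number of the 12393 genes higher and lower than in untreated cells (vertical axis, bars from 0) at each dose of each particle size (horizontal axis), at limma's adjusted p under 0.05.

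Compared directly at the high doses, cells given 10 nm silica had more of several transcription factor mRNAs than cells given 500 nm silica. Klf2 was 6.74-fold higher with 10 nm (log2 difference 2.75 ± 0.13 SE, n = 3 arrays each, limma adjusted p = 2.17e-10). Egr2 was higher 5.34-fold (2.42 ± 0.15, adjusted p = 4.08e-09), Nr4a1 5.06-fold (2.34 ± 0.18) and Nr4a2 4.98-fold (2.32 ± 0.13). Malat1, a long noncoding RNA of the nucleus, was 5.64-fold higher (2.5 ± 0.34, adjusted p = 0.000123). Higher with 500 nm were Slc7a11 by 4.46-fold (-2.16 ± 0.13, adjusted p = 2.87e-09), the linker histone gene H1f2 by 4.21-fold (-2.07 ± 0.11) and Slc40a1 by 3.82-fold (-1.94 ± 0.21). Ccrl2 was higher with 500 nm by 3.61-fold (-1.85 ± 0.13) and Chst10 by 3.42-fold (-1.77 ± 0.40, adjusted p = 0.00805; SD 1.0 over the 10 nm arrays). Slc7a11 stood at 7.27 ± 0.04 in untreated cells, 7.23 ± 0.16 with 10 nm and 9.39 ± 0.29 with 500 nm silica (SD). Among other probe sets of H1f2 the log2 difference ranged from -1.62 to 0.10.

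The sizes differed at their high doses in 932 genes (418 higher with 10 nm and 514 with 500 nm), 92 of them by at least 2-fold (53 and 39). With the replicate block the count was 2071 (784 and 1287). More genes were higher with 10 nm after quantile normalization (577 and 501) and rescaling (522 and 476), over all probe sets (828 and 692) and in the fit on these groups alone (95 and 68). The split was 350 and 302 without 10 nm high dose replicate 3, and 278 and 265 (543 in all) and 280 and 285 (565) without 500 nm high dose replicates 1 and 2.

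Of the sterol synthesis genes, 0 were higher with 10 nm and 12 of 20 with 500 nm silica (0 and 14 adjusted over the list alone), among them Hmgcs1 (-0.95) and Sc5d (-1.06; its other probe set 0.25). The median was -0.62 (adjusted p = 4.8e-16, 6.87e-05 estimated). Of the NF-kB pathway feedback genes, 1 and 14 of 24 differed (1 and 19 adjusted over the list alone), with Rel (-1.46) and Traf1 (-1.14) higher with 500 nm. The median was -0.50 (adjusted p = 9.61e-15, 0.00213 estimated). Of the immediate early genes, 9 were higher and 1 lower with 10 nm (11 and 2 adjusted over the list alone), Fos (1.41) among the former and Maff (-1.16) the latter. The median was 0.30 (adjusted p = 4.48e-08, 0.0169 estimated). Another 4 lists differed with the preset correlation alone, and 6 lists passed estimated after rescaling. NRF2 antioxidant genes gave 0 higher and 3 lower of 21, 0 and 7 adjusted over the list alone, median -0.26, adjusted p = 0.000848, 0.0722 estimated. LXR targets gave 4 higher and 1 lower of 17, 7 and 2 adjusted over the list alone, median 0.23, adjusted p = 0.0338, 0.0722 estimated. Oxidative phosphorylation gave 0 higher and 2 lower of 31, 0 and 3 adjusted over the list alone, median -0.27, adjusted p = 0.000368, 0.312 estimated. Transcription regulators gave 5 higher and 1 lower of 28, 6 and 1 adjusted over the list alone, median 0.11, adjusted p = 0.0338, 0.185 estimated. The lysosome and actin lists did not pass as deposited and passed after quantile normalization (0.0142 and 0.0493), centring (0.0499 and 0.0499) and rescaling (0.00563 and 0.0184).

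At equal nominal surface area, the 10 nm mid dose against the 500 nm high dose, Klf2 was 7.45-fold higher with 10 nm silica (2.90 ± 0.13, limma adjusted p = 8.61e-11), Rhob 5.04-fold (2.33 ± 0.27) and Nr4a1 4.63-fold (2.21 ± 0.18). H1f2 (-2.06 ± 0.11), Slc7a11 (-1.77 ± 0.13) and Slc40a1 (-1.68 ± 0.21) were higher with 500 nm. In all, 353 genes differed (224 higher with 10 nm and 129 with 500 nm; 35 at least 2-fold, 22 and 13). The count was 191 (125 and 66), 192 (107 and 85) and 223 (145 and 78) without 10 nm mid dose replicate 1, 2 and 3, and 195 (129 and 66) and 213 (121 and 92) without 500 nm high dose replicate 1 and 3. Array weights gave 959 and 1295. Counting members higher and lower with 10 nm, 0 and 9 of 20 sterol genes differed (0 and 12 adjusted over the list alone; median -0.39, adjusted p = 2.59e-11, 0.000602 estimated). Of the NF-kB genes 1 and 9 of 24 differed (1 and 16 adjusted over the list alone; median -0.46, adjusted p = 6.24e-16, 0.00133 estimated). Of the immediate early genes 9 and 2 of 32 differed (14 and 2 adjusted over the list alone; median 0.38, adjusted p = 3.24e-12, 0.00268 estimated). The list tests of this pair and of the low doses were added after the data were examined.

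At the low doses, Hbegf was 2.73-fold higher with 10 nm than with 500 nm silica (1.45 ± 0.18, limma adjusted p = 0.00139), and Phlda1 (1.35 ± 0.21, adjusted p = 0.00605) and Egr2 (1.12 ± 0.15, adjusted p = 0.00139) were also higher. Cd28 was lower with 10 nm (-0.77 ± 0.14, adjusted p = 0.0272). The call of Phlda1 ended without replicate 2 of 10 nm (adjusted p 0.0518) or 500 nm (0.0856). Without replicate 1, 2 or 3 that of Cd28 ended (0.273, 0.0807 and 0.051 for 10 nm, 0.0687, 0.151 and 0.205 for 500 nm). In all, 11 genes differed (10 higher and 1 lower with 10 nm; 3 at least 2-fold), and 6 without replicate 2 of either group. Of the lists, 8 passed with the preset correlation and 3 with the estimated one, namely cytokines, NF-kB and immediate early genes. Quantile normalization, rescaling and the block gave 7, 8 and 5 estimated. The 3 prime minus 5 prime signal was 1.09 to 1.30 with 10 nm and 0.60 to 0.93 with 500 nm.

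**Figure D5:**
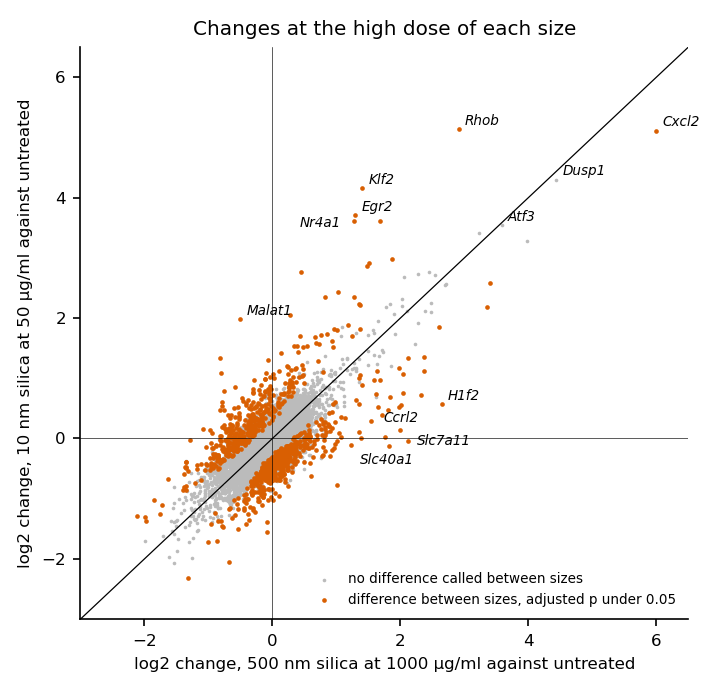
Log2 change of each of 12393 genes against untreated cells at the 10 nm high dose and the 500 nm high dose, one size per axis, with the line of equal change; orange points are the 932 genes with an adjusted p under 0.05 between the sizes.

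Many of the same genes changed with both sizes. At the high doses, 320 genes were called higher with both (49.9 for independent lists) and 780 lower with both (157), while 13 were called in opposite directions. The shared calls were 263 and 634 for the 10 nm mid and 500 nm high doses (21.2 and 91.7 for independent lists; 4 opposite) and 35 and 3 for the low doses (0.26 and 0.016; 0 opposite). Across genes, which are not independent replicates, the log2 changes correlated at r = 0.741 at the high doses, 0.819 for the equal-area pair and 0.68 at the low doses. Unchanged groups simulated against the same 3 untreated arrays gave 0.498, 0.50 and 0.501. With the 3 prime minus 5 prime signal as a covariate, a fit that was not simulated, the low-dose correlation was 0.432, below that value. The covariance was 0.118, 0.111 and 0.0221 against 0.0157 in the simulations. The 3 untreated arrays cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

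Markers of macrophages were bright in untreated cells (mean 10.8 on the log2 scale) and markers of other cell types were dim, apart from 6 of 57 above the median of all genes (Ighm at 11.39). At the 10 nm high dose, the macrophage markers had a median log2 change of -0.18 (1 of 13 higher and 2 lower, adjusted p = 0.313), and at the 500 nm high dose -0.15 (adjusted p = 0.38). At the 10 nm and 500 nm high doses the medians of the other lists, with the adjusted p, were 0.35 and 0.25 for neutrophil (0.0878 and 0.128), 0.20 and 0.21 for dendritic cell (0.159 and 0.156), 0.21 and 0.16 for T cell (0.321 and 0.468), 0.32 and 0.33 for B cell (0.321 and 0.38), 0.28 and 0.18 for fibroblast (0.0878 and 0.128), 0.17 and 0.28 for epithelial (0.262 and 0.128) and 0.36 and 0.22 for osteoclast markers (0.0878 and 0.128). None of the 8 marker lists passed with camera at these doses, while fry, which tests a list against no change and not against other genes, called osteoclast markers at both (adjusted p = 0.00101 and 0.00156) and epithelial markers at the 500 nm high dose (adjusted p = 0.0233). With the preset correlation alone, neutrophil and T cell markers passed at the 500 nm low (0.0171 each) and mid dose (0.0496 each), and T cell markers between the low doses (0.0252, adjusted p). Over all 57 markers of other cell types, the medians were 0.12, 0.16 and 0.28 at the 3 doses of 10 nm and 0.11, 0.13 and 0.23 at those of 500 nm silica, and 6 were called higher and 2 lower at the 10 nm high dose.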

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

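The tests weighed below of the replicate 3 arrays, of the markers of other cell types and of the lists that differed between sizes, and the list tests at the low and equal-area doses, were chosen only after the results were seen. The counts over other splits of the arrays were planned. The results below stood out because the 2 particle sizes differed when tested against each other with limma, by gene or list. The genes that differed numbered 932 at the high doses, 353 at equal nominal area (10 nm mid against 500 nm high) and 11 at the low doses. In the lists below, the values are the median log2 difference (10 nm minus 500 nm), the adjusted p with an estimated correlation, and the 10 nm arrays whose list median lay beyond all 500 nm arrays in that direction. At the high doses, 7 lists differed with the preset correlation, of which 3 also passed with the estimated one, namely NF-kB feedback genes (-0.50, 0.00213, 3 of 3), immediate early genes (0.30, 0.0169, 3 of 3) and sterol synthesis (-0.62, 6.87e-05, 3 of 3). The calls of NRF2 genes (-0.26, 0.0722, 3 of 3), LXR targets (0.23, 0.0722, 3 of 3), oxidative phosphorylation (-0.27, 0.312, 3 of 3) and transcription regulators (0.11, 0.185, 3 of 3) were lost, the second value being that adjusted p. At equal nominal area 9 lists differed, 6 of them with both correlations, namely NF-kB feedback genes (-0.46, 0.00133, 3 of 3), immediate early genes (0.38, 0.00268, 3 of 3), sterol synthesis (-0.39, 0.000602, 3 of 3), LXR targets (0.10, 0.0478, 2 of 3), actin and SRF targets (0.036, 0.0238, 3 of 3) and transcription regulators (0.056, 0.0478, 3 of 3). The calls of NRF2 genes (-0.16, 0.06, 3 of 3), lysosome genes (0.13, 0.0645, 2 of 3) and hypoxia genes (0.063, 0.317, 3 of 3) were lost with that adjusted p. At the low doses 8 differed and 3 passed both, namely cytokines (0.11, 0.00746, 1 of 3), NF-kB feedback genes (0.21, 0.0288, 3 of 3) and immediate early genes (0.23, 0.00493, 3 of 3). The calls of NRF2 genes (-0.055, 0.169, 1 of 3), hypoxia genes (0.092, 0.056, 0 of 3), growth factors (0.13, 0.056, 2 of 3), actin and SRF targets (0.12, 0.056, 3 of 3) and transcription regulators (0.061, 0.0619, 2 of 3) were lost with that adjusted p. With the estimated correlation 3, 7 and 7 lists passed after quantile normalization and 6, 8 and 8 after rescaling, in the same order. The sign of each of these medians was kept after quantile normalization, centring and rescaling. Centring ended the calls with the estimated correlation at equal area for LXR (0.0513), actin (0.0674) and transcription regulator genes (0.0674), as did quantile normalization for LXR (0.0649, adjusted p).

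Of the 98 named genes, 55 differed between the high doses. The 29 higher with 10 nm silica, by log2 difference, were Klf2 (2.75), Malat1 (2.5), Egr2 (2.42), Nr4a1 (2.34), Nr4a2 (2.32), Rhob (2.23), Ccl2 (1.93), Arc (1.77), Olr1 (1.42), Fos (1.41), Ndrg1 (1.38), Mt2 (1.26), Klf4 (1.11), Hspa1b (1.08), Calcrl (0.94), Mki67 (0.85), Abca1 (0.83), Calhm2 (0.83), Bcl2l11 (0.69), Akr1b10 (0.69), Cenpf (0.69), Sgpp1 (0.62), Ptpro (0.60), Dnajb1 (0.58), Plin2 (0.57), Cmpk2 (0.54), Themis2 (0.50), Cdc6 (0.47) and Sertad1 (0.45). The 26 higher with 500 nm silica were Ndufs1 (-0.29), Scd2 (-0.53), Atp6v1h (-0.63), Txnip (-0.71), Srxn1 (-0.71), Gadd45b (-0.82), Stambp (-0.83), Cxcl2 (-0.88), Hmgcs1 (-0.95), Zfp958 (-1.0), Sc5d (-1.06), Clec4e (-1.12), Traf1 (-1.14), Maff (-1.16), Plau (-1.25), Trib3 (-1.33), Tent5c (-1.34), Pde4b (-1.37), Ddit3 (-1.45), Rel (-1.46), Cxcl10 (-1.74), Chst10 (-1.77), Ccrl2 (-1.85), Slc40a1 (-1.94), H1f2 (-2.07) and Slc7a11 (-2.16). Calls ended, with limma's adjusted p in parentheses, without 10 nm high dose replicate 1, Bcl2l11 (0.0794) and Ndufs1 (0.0673); without 10 nm high dose replicate 2, Cmpk2 (0.0979), Bcl2l11 (0.0561) and Ndufs1 (0.123); without 10 nm high dose replicate 3, Dnajb1 (0.072), Abca1 (0.129), Cdc6 (0.0657), Cmpk2 (0.0981), Bcl2l11 (0.117) and Ndufs1 (0.105); without 500 nm high dose replicate 1, Abca1 (0.0515), Bcl2l11 (0.105) and Ndufs1 (0.175); without 500 nm high dose replicate 2, Dnajb1 (0.0914), Abca1 (0.147), Cdc6 (0.0558), Cmpk2 (0.0997), Txnip (0.0561), Bcl2l11 (0.148) and Ndufs1 (0.0795); without 500 nm high dose replicate 3, Cmpk2 (0.0583) and Ndufs1 (0.0883). Other probe sets of Abca1, Bcl2l11, Calcrl, Clec4e, H1f2, Sc5d, Scd2, Sgpp1 and Srxn1 included one of the opposite sign. At equal nominal area Klf2 (2.90), Rhob (2.33), Nr4a1 (2.21), H1f2 (-2.06), Slc7a11 (-1.77) and Slc40a1 (-1.68) differed. At the low doses Hbegf (1.45), Phlda1 (1.35), Egr2 (1.12) and Cd28 (-0.77) differed. The call of Phlda1 ended without replicate 2 of 10 nm (adjusted p 0.0518) or 500 nm (0.0856). Without replicate 1, 2 or 3 that of Cd28 ended (0.273, 0.0807 and 0.051 for 10 nm, 0.0687, 0.151 and 0.205 for 500 nm).

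Each comparison of 3 arrays with 3 has 10 splits of its 6 arrays, the real one included, which is too few for a share under 0.05. The real counts were 95, 1315 and 2506 genes for 10 nm low, mid and high, 53, 343 and 1898 for 500 nm low, mid and high, 11 for the low doses against each other and 353 for the equal-area pair, and the highest other split gave 0 in each of these 8. Between the high doses the real count was 932 and the highest other 7, and the highest was 0 among the other splits that part all pairs of the same replicate number. For the gene lists, the real and highest other counts were 9 and 6 at the 10 nm high dose, 13 and 11 at the 500 nm high dose and 7 and 8 between them. In the last case 3 of the 10 splits gave at least 7 lists, the others being 10 nm replicate 1 with 500 nm replicates 1 and 2, and 10 nm replicates 1 and 3 with 500 nm replicate 3, each with a pair of the same number on one side. Among the other splits that part all pairs the highest list counts were 5, 7 and 4. The dose trends had 1509 genes with 10 nm and 1016 with 500 nm, against at most 413 and 344 in other groupings of the 9 arrays. Only the real one of 100 gave as many. This excludes chance assignment of arrays, not chance differences between cultures, and ignores replicate numbers.

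Replicate 3 arrays deviated from their group means together: their deviations correlated at a mean of 0.586 across genes, which are not independent, against 0.432 for replicate 2, 0.112 for replicate 1 and -0.182 for arrays of different numbers. A spread left by the authors' normalization was excluded as the whole cause, since after quantile normalization the mean was 0.533 and the lowest pair 0.397. RNA integrity stays open: over the 21 arrays the 3 prime minus 5 prime signal went with the first component (both as deviations from the group mean) at Pearson's r = 0.852 (permutation p = 0.00252) and Spearman's rho = 0.851 (permutation p = 0.00121), and at r = 0.769 without the 2 arrays farthest from the median signal, and removing that signal lowered the mean replicate 3 correlation to 0.111 (lowest pair -0.664), yet replicate 3 had the highest signal in 4 of 7 groups only. A shared day or batch of the number also stays open, as 12 of 21 arrays correlated best with an array of their own number in another group; the labels name no batch, so it and RNA integrity cannot be told apart. No biological explanation was tested, because every group holds 1 array of each number.

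Markers of 7 other cell types lay above their untreated level as a set at the high doses, with a median of 0.28 over 57 genes (SD 0.27) at the 10 nm and 0.23 (SD 0.22) at the 500 nm high dose, although no list passed with camera (lowest adjusted p with an estimated correlation 0.37 at the 10 nm high dose); 6 of the 57 lay above the median brightness of all genes in untreated cells and 2 are also in a gene list. RNA of other cell types stays open: at the 10 nm high dose 61 smell and pheromone receptor genes, which such cells do not express, had a median of 0.272 (SD 0.211), but these are dim genes too. At that dose 5 of the 6 bright markers lay lower (Ighm at log2 11.39, Nfatc1 9.58 and Tnfrsf11a 7.68 brightest). They exclude nothing, as a high baseline hides a small share. A general rise of dim genes also stays open, and the receptor genes go with it. Against it, the markers lay at percentile 99.9 of 10000 random lists matched on brightness (median 0.186), which treats genes as independent. The spread left by the authors' normalization stays open: quantile normalization lowered the median to 0.112 (SD 0.234, percentile 99.8). For the 500 nm high dose the same values were 0.191 for the receptors, percentile 99.4, and 0.071 after quantile normalization (percentile 96.6). A response of these genes to silica stays open and was not tested.

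The sterol synthesis and NF-kB feedback lists were higher with 500 nm and the immediate early genes higher with 10 nm silica at the high doses (medians -0.62, -0.50 and 0.30; the 3 arrays of one size lay beyond the 3 of the other in each list). A difference in nominal surface area was excluded as the whole cause, since at equal area the medians were -0.39, -0.46 and 0.38 and the largest adjusted p of the 3 lists with an estimated correlation was 0.00268. RNA integrity was excluded as the whole cause by a largest adjusted p of 0.0275 over the fit with the 3 prime minus 5 prime covariate and the fit without replicate 3 arrays (medians -0.63, -0.51 and 0.36, and -0.63, -0.47 and 0.35). The spread left by the authors' normalization was excluded as the whole cause by a largest adjusted p of 0.000947 after quantile normalization (medians -0.56, -0.51 and 0.34). Over these fits adjusted p ranged from 1.01e-05 to 0.0275. With the replicate block it was 0.000168, 0.00809 and 0.0213. Particle size is a candidate explanation, but each size had its own range of masses, and mass, particle number and size cannot be separated here.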

How the results depend on the processing

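The fits without all replicate 3 arrays, with the 3 prime minus 5 prime signal as a covariate and with rescaled arrays were chosen after the data were examined, and the other alternatives were planned. Counts of changed genes are given in the order 10 nm low, mid and high, 500 nm low, mid and high, 10 nm trend, 500 nm trend, then 10 nm against 500 nm at the low doses, at equal area and at the high doses. As analysed they were 95, 1315, 2506, 53, 343, 1898, 1509, 1016, 11, 353 and 932. With a trended and robust prior, without the dimmest 40% of genes, after quantile normalization, with centred or rescaled arrays and with the mean of a gene's probe sets, each of the 11 counts stayed within 1.5 times the count as analysed. Without the dimmest 40% the 10 nm high dose gave 584 higher and 1642 lower genes. A block for the replicate number gave 214, 2235, 4544, 110, 710, 3433, 2821, 1923, 37, 789 and 2071, and the signal covariate 275, 2106, 4338, 116, 568, 3285, 3652, 1997, 31, 819 and 1811, with a correlation of the 2 sizes across genes of 0.432 at the low doses. Array weights gave 1219, 3152, 6254, 371, 2317, 4854, 4129, 3346, 136, 2254 and 4766, with a correlation of 0.775 for the equal-area pair; the estimation of the weights stopped before it converged, with the lowest weights for untreated replicate 3 (0.163) and 10 nm high dose replicate 3 (0.155). The cause of these moves was not tested. Fits on the compared groups alone, which estimate the spread from fewer arrays, gave 28, 658, 692, 13, 124, 761, 926, 1217, 15, 97 and 163. All probe sets taken singly, which count several per gene, gave 140, 2089, 3983, 76, 565, 3240, 2415, 1809, 11, 629 and 1520, with a correlation of 0.795 for the equal-area pair. By construction, stricter thresholds lowered the counts. An adjusted p under 0.01 gave 60, 794, 1281, 34, 182, 1046, 762, 548, 8, 158 and 453. A log2 change of at least 1 (for trends, slope per doubling) was then required at an adjusted p under 0.05. It left 19, 210, 281, 14, 60, 252, 6, 18, 3, 35 and 92. Without all replicate 3 arrays 7 genes differed at the low doses, and the equal-area correlation was 0.794, with fewer arrays in the fit; the other counts stayed within 1.5 times.

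Leaving out each array in turn gave ranges of 60 to 96, 877 to 1196, 1763 to 3034, 35 to 50, 216 to 298, 1381 to 1720, 837 to 1682, 646 to 986, 6 to 11, 191 to 256 and 543 to 906 in the same order. A group left with 2 arrays shares the spread estimated over all groups; fewer arrays lower counts by construction, and the cause of higher counts and of moved correlations was not tested. The correlations ranged from 0.585 to 0.782 at the low doses, 0.785 to 0.843 at equal area and 0.649 to 0.765 at the high doses, and stayed positive under all alternatives. The lists past the threshold at the 10 nm high dose, the 500 nm high dose and between them numbered 9, 13 and 7 as analysed, 3, 6 and 3 with camera's estimated correlation and 17, 15 and 11 with fry, which tests against no change, and the cause of these moves was not tested. They ranged over 7 to 10, 10 to 13 and 5 to 10 without single arrays.

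Deviations of same-number arrays did not all correlate above 0.1 in the other comparisons, so those were not treated as paired. For replicates 1, 2 and 3 they were 0.0671, 0.313 and 0.479 for 10 nm low, -0.0264, 0.315 and 0.425, -0.24, 0.484 and 0.459 and 0.0102, 0.509 and 0.556 for 500 nm low, mid and high (each with untreated cells), 0.0887, 0.169 and 0.47 for the low doses, 0.0361, 0.526 and 0.716 for equal area, 0.00473, 0.337 and 0.583 for 10 nm low with high and 0.0474, 0.719 and 0.627 for 500 nm mid with high. Of the 21 arrays, 12 correlated best with an array of their own number in another group. With the block, 1 and 4 list calls were gained and lost at the preset and 7 and 2 at the estimated correlation in these comparisons. Of the named gene results, 16 became called with the block, namely Plk2, Hmox1, Hsd17b7, Aurkb, Ccne2, Sesn1, Ctsl, Lamp2, Tlr4, Naip5, Atp5c1 and Klf9 between the high doses and Dnajb1, Ctsl, Tagln and Rpl14 at the 500 nm high dose, and 0 calls were lost. Apart from these and the 2 list calls given for the 10 nm mid dose, the block changed no call of a list or named gene, and the cause of the changes was not tested.

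The named genes gave 265 results, 217 of them called. Over all alternatives, 4921 of 5315 recomputed values kept their direction and their side of the threshold, 256 lost the call, 92 gained it and 46 changed sign; for single arrays left out the numbers were 1524 of 1626, 76, 10 and 16. The sign changes concerned 15 results, none called before or after, with a log2 value as analysed of at most 0.22 in size, and their cause was not tested. Where no comparison is named, they are at the 10 nm high dose. Quantile normalization gave the other sign for Slc7a11 (0.16), Sc5d (0.033), Cenpf (0.13), Atp6v1h (0.084) and Cxcl10 (-0.067). Centring did so for Slc7a11 (0.070), Sc5d (0.021), Cenpf (0.080) and Atp6v1h (0.062), and at the 500 nm high dose for Ndufs1 (0.029) and Atp5c1 (0.058). Rescaling did so for Sc5d (0.016), Cenpf (0.045), Lamp2 (0.0069), Atp6v1h (0.041) and Cxcl10 (-0.034), and at the 500 nm high dose for Ndufs1 (0.027) and Atp5c1 (0.11), and the mean of probe sets for Hmgcs1 (-0.025), Sc5d (0.060) and Cenpf (0.012), and between the high doses for Pdk1 (0.018). Array weights did so for Atp6v1h (0.084), at the 500 nm high dose for Ndufs1 (0.0059) and between the high doses for Slc30a1 (0.014), Tyms (0.065) and Tagln (-0.034). The fit without replicate 3 arrays did so for Atp6v1h (0.021) and between the high doses for Tyms (0.020), and the signal covariate for Cxcl10 (-0.013). Without single arrays, the values spanned 0 for Atp6v1h -0.16 to 0.12, Cxcl10 -0.21 to 0.25, Hmgcs1 -0.090 to 0.34, Lamp2 -0.34 to 0.039, Sc5d -0.19 to 0.032, Slc40a1 -0.32 to 0.17, Slc7a11 -0.12 to 0.041, and between the high doses Sesn2 -0.0059 to 0.35 and Tyms -0.12 to 0.065. The deposited values carry no background or detection measure, and RMA compresses changes near background, so for dim genes a change that was not called was not detectable at this signal, and no gene can be called absent.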

Other observations

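The genes and families in this part and the Zfp test were chosen after their values were seen. Values are log2 changes with limma's adjusted p over 12393 genes, n = 3 arrays per group. The linker histone gene H1f2 stood at 0.27, 0.59 and 0.57 over the 10 nm doses (adjusted p 0.576, 0.00143 and 0.00129) and 0.15, 1.24 and 2.64 over the 500 nm doses (0.999, 8.36e-07 and 3.98e-12), and the difference between the high doses was -2.07 (adjusted p 8.54e-10). Among other histone genes, H3c4 went the other way between the sizes, with 0.99, 1.4 and 1.52 over the 10 nm doses (adjusted p 0.00745, 2.68e-05 and 8.19e-06) and 1.72, 0.26 and 0.48 over the 500 nm doses (2.42e-05, 0.662 and 0.0849), and was higher with 10 nm at the high doses by 1.04 (adjusted p 0.00134). Its change at the 500 nm high dose was called with adjusted p 0.0374 without 500 nm high dose replicate 2, and with centred arrays (0.0418). H3c7 gave 0.61, 0.99 and 0.97 over the 10 nm doses (adjusted p 0.0619, 9.27e-05 and 8.59e-05) and 0.84, 0.21 and 0.27 over the 500 nm doses (0.00643, 0.656 and 0.233) and a difference of 0.70 (0.00483). H2aw was higher with 500 nm, like H1f2 (-1.25, adjusted p 0.0061), while H2bc18 (0.44, 0.0784) and H2bc22 (-0.28, 0.567) were not called. In the differences between the high doses of H1f2, H2aw, H3c4, H3c7 and H2bc18 the 3 arrays of each size did not overlap, while those of H2bc22 did, and the 6 signs were kept after quantile normalization, centring and rescaling.

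Among long noncoding RNAs, Malat1 gave 1.12, 1.57 and 1.99 over the 10 nm doses (adjusted p 0.238, 0.00437 and 0.000384) and 1.02, 0.0040 and -0.51 over the 500 nm doses (0.485, 0.997 and 0.339), with a difference of 2.5 between the high doses (adjusted p 0.000123). The lower value at the 500 nm high dose was called with adjusted p 0.0168 without untreated replicate 1, and the untreated arrays had an SD of 1.10. Lncpint gave 0.084, 0.64 and 1.09 over the 10 nm doses (adjusted p 0.983, 0.0316 and 0.000345) and 0.49, -0.35 and -0.81 over the 500 nm doses (0.625, 0.481 and 0.00531), and a difference of 1.90 (2.87e-06); its call at the 10 nm mid dose ended after quantile normalization (0.0944). Neat1 gave 0.54, 0.12 and -0.070 over the 10 nm doses (adjusted p 0.0786, 0.667 and 0.727) and -0.34, -0.73 and -0.97 over the 500 nm doses (0.645, 0.00298 and 3.95e-05). It was called at the 10 nm low dose after quantile normalization (0.00942) and rescaling (0.012), and at the 10 nm high dose its sign turned positive after quantile normalization, centring and rescaling (0.011, 0.036 and 0.071). Neat1 was higher with 10 nm than with 500 nm silica by 0.90 at the high doses (adjusted p 0.000244) and by 0.88 at the low doses (0.00587, and 0.0597 without 10 nm low dose replicate 2 and 0.0594 without 500 nm low dose replicate 3). In these differences all 3 arrays of 10 nm silica lay above all 3 of 500 nm silica. The signs of the differences were kept after quantile normalization, centring and rescaling.

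Grouping genes by the letters that start their symbols gave 139 families of at least 10 genes, tested with camera and adjusted over the families. At the 10 nm high dose, the 500 nm high dose and between them, 14, 6 and 8 families passed with the preset and 2, 0 and 1 with the estimated correlation. The Klf transcription factors, which share members with the immediate early and transcription regulator lists, had a median of 0.40 at the 10 nm high dose (6 of 14 higher, 0 lower, adjusted p = 1.42e-05, and 0.0107 with the estimated correlation). Between the high doses it was 0.40 (4 higher with 10 nm, 0 with 500 nm, adjusted p = 2.51e-06, and 0.00608). In both the family median of all 3 arrays given 10 nm lay above the other 3, and quantile normalization, centring and rescaling gave 0.45, 0.51 and 0.39, and 0.43, 0.41 and 0.41. At the 500 nm high dose the median was 0.17 (adjusted p = 0.129). The Ccl chemokines had medians of 0.25 at the 10 nm high dose (5 of 18 higher, adjusted p = 0.000713, and 0.0207 with the estimated correlation, 3 of 3 arrays above) and 0.23 at the 500 nm high dose (4 higher, 0.00825, and an adjusted p of 0.149 with the estimated correlation, 2 of 3 arrays above), positive in all 3 scalings.

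A hypothesis was that the 173 genes of the Zfp family, zinc finger genes, fell beyond equally bright genes. Of them, 52 and 45 were lower at the 10 nm and 500 nm high doses, against 22.3 and 18.1 expected from equally bright genes, and 7 and 5 were higher. The medians were -0.17 (SD 0.523) and -0.12 (SD 0.474), with all 3 treated arrays below the untreated ones. They lay below all 10000 random lists matched on brightness (medians 0.074 and 0.083), which treat genes as independent. They stayed negative after quantile normalization (-0.15 and -0.16), centring (-0.063 and -0.032) and rescaling (-0.21 and -0.21). The adjusted p was 0.0012 and 0.00302 with the preset correlation, and 0.464 and 0.414 with the estimated one, so the test leaves the hypothesis undecided: a shift of the family cannot be told apart from members that vary together between arrays.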
